A study of Arabidopsis thaliana with 3 samples.

How the data were processed

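The series holds 3 ChIP-seq samples of Arabidopsis thaliana accession Col-0. Per the labels, seedlings grown in the dark for 4 days in hydroponics were given 10 uM dexamethasone for 6 h, a glucocorticoid widely used to switch on inducible transgenes. Crosslinked chromatin of whole seedlings was sheared to fragments of 100 to 500 bp and precipitated with an antibody against GFP. The samples expressed GFP alone (the control), a GFP fusion of DIG1, or a GFP fusion of DIG2, with 1 sample per group. Libraries were sequenced on an Illumina instrument. A peak list was analysed for DIG1 and for DIG2; no list of the GFP sample was used here.

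Per the submitters' processing notes, the aligner Bowtie 0.12.7, the TAIR10 build and the peak caller MACS2 were used, and the MACS2 version is not given in the sources used here. The lists are in the narrowPeak layout. Per the layout of the deposited lists, each summit carries the authors' fold enrichment over the modelled background (a ratio), the authors' −log10 p and −log10 q, and a score. The deposited score equalled 10 times the −log10 q rounded down to a whole number for 13459 of 13459 DIG1 summits and 16561 of 16562 DIG2 summits, and it was not used further. No deposited −log10 p lay under 16. Whether replicates were pooled before calling, which control each list was called against, and the read depth of each library are not given in the sources used here. Depth therefore cannot be compared between the lists, and the authors' values were used only to rank, filter or describe peaks within their own list.

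An interval with several summits is repeated in the deposited lists, once per summit. A peak here is a distinct interval, placed at its strongest summit and ranked by the authors' −log10 p of that summit. Coordinates are those of the deposited lists on TAIR10, counted from 1. Gene names and neighbourhoods came from a RefSeq gene table of assembly TAIR10.1 with 38312 entries, of which 27444 nuclear protein-coding genes were used. No coordinate of that table is printed. To check that its genes lie where the lists assume them, summits were shifted in steps of 50 bp, up to 2000 bp each way, and the number inside genes was counted. The fewest fell inside genes at shifts between -50 and 50 bp in all 10 combinations of list and chromosome, and between -100 and 50 bp in 48 blocks of 5 Mb. The table gives neither strand nor exons. The planned promoter and transcript classes were therefore replaced by rules that treat both gene ends alike. A gene counted as having a summit at its end when any summit lay from 1000 bp outside to 200 bp inside either end, and a peak was classed as inside a protein-coding gene, outside and at most 1000 bp from a gene end, or farther. Exons, introns and untranslated regions were not told apart. The planned motif search at summits was not run, since no genome sequence was used here.

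Peaks were partners when they shared at least 50 percent of the shorter one. Sharing and position were set against 1000 random placements of the peaks on their own chromosome with bedtools 2.31.1, without overlap among placed peaks, with a one-sided permutation p for overlap and a two-sided one for position. The smallest p these can give are 0.001 and 0.002. Placement used whole chromosomes, and sequence in which reads cannot be placed was not left out. The random shares for overlap and position can be off for this reason. Position p-values were adjusted by Benjamini-Hochberg over 18 tests. Gene sharing, and partners in the strongest against the weakest 20% of each list, were tested with Fisher's exact test, two-sided. The 26 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Of the 300 list members given by locus, 1 (RVE6) was left out because the table does not hold that name for its locus. Each list was tested against all other genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 52 tests and calls at adjusted p under 0.05. DIG1 and DIG2 were compared within each list by an exact McNemar test on genes with a summit in 1 of the lists, adjusted over 26 lists. Shares carry 95% Wilson intervals, which cover counting error only.

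Named genes were those at the 10 strongest peaks of each list, those at the 5 strongest peaks that touched no peak of the other list, up to 3 members per gene list with the strongest peaks, members without a summit where a list had 4 or fewer, and the labelled genes. Genes outside this rule that are named were chosen after their values were seen, and some genes within it are not reported here. The alternatives were a stricter threshold of 30 for −log10 p, lists of equal length (11343 peaks), the 1000 strongest peaks, other overlap rules, placement relative to gene ends, other gene windows, 10000 random lists matched on flanking intergenic length, other promoter widths, peak midpoints and ranking by fold. Others were added after seeing the data: the strongest summit alone, every deposited summit, overlap by 1 bp in the ranking, a Fisher test between the factors, and a cleaned list of ribosomal genes.

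The code was tested on simulated data. For 11343 intervals with 60.2% planted partners and 61.6% expected after chance contacts, 61.8% were recovered. On the 27444 genes, lists planted at a share of 75% were called in 42 of 100 draws for 7 genes and 77 for 20 genes. The numbers were 93 for 25 genes, 92 for 27 genes and 100 for 71 genes. Of tests on lists without planted genes, 0.941% were called. Each gene was drawn independently, so the rate of false calls for lists of neighbouring genes that share summits was not simulated. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.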

Results

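Binding sites of the Arabidopsis proteins DIG1 and DIG2 were mapped by ChIP-seq of GFP fusions in dark-grown seedlings given dexamethasone for 6 h, within a series on transcription factors of the response to the hormone abscisic acid (ABA). The DIG1 list held 13459 summits in 11343 peaks and the DIG2 list 16562 summits in 13440 peaks. The median peak was 591 bp wide for DIG1 and 577 bp for DIG2, and peaks covered 8.18 and 9.71 Mb. The authors' fold enrichment of summits ranged from 1.61 to 16.7 in the DIG1 list and from 1.70 to 20.5 in the DIG2 list. Peaks lay on all 5 nuclear chromosomes, at 89.5 to 99.4 per Mb for DIG1 and 106 to 117 per Mb for DIG2. There was 1 list per factor and no replicate list, so p-values describe these lists and not the spread between experiments, and read depth was unknown.

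The first question was whether DIG1 and DIG2 occupied the same regions. Of the 11343 DIG1 peaks, 10996 (96.9%, 95% Wilson interval 96.6 to 97.2%) had a partner in the DIG2 list. Of the 13440 DIG2 peaks, 10768 (80.1%, 79.4 to 80.8%) had a partner in the DIG1 list. Random placement gave means of 10.4% and 8.73% and maxima of 11.3% and 9.52% (one-sided permutation p = 0.001 for both, the smallest that 1000 placements can give). Where a DIG1 peak touched a DIG2 peak, the strongest summits of the pair were a median of 11 bp apart, and 93.3% were within 100 bp. Both precipitations used the same antibody and may have used a common control, so part of the excess over random placement can come from what they share.

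The strongest peaks of both lists lay at many of the same genes. The DIG1 peak with the highest −log10 p was at ABF3 (AT4G34000), which encodes a bZIP transcription factor of the ABA response. It spanned chromosome 4, 16294217 to 16295686 (TAIR10), with its summit 92 bp outside the gene and a fold of 15.6. The same gene held the DIG2 peak of rank 9 (fold 16.7, summit 91 bp outside). The top DIG2 peak (chromosome 3, 2439764 to 2441839, fold 19.4) was at COL9 (AT3G07650), a CONSTANS-like zinc-finger gene, 256 bp outside it, and COL9 held rank 4 in the DIG1 list with a fold of 16.5. Both sets of 10 also held peaks at AT5G13100, at AT3G48140, beside AT3G61420 and the aquaporin gene PIP1A (AT3G61430), at 1265 and 1263 bp from the AP2/B3 factor gene RAV1 (AT1G13260), and at 3162 and 3173 bp from the NAC factor gene ANAC087 (AT5G18270). The rest of the DIG1 set lay at AT4G33080, AT1G62870 and 1039 bp from FLP1 (AT4G31380). The rest of the DIG2 set lay beside AT4G28030 and UMAMIT33 (AT4G28040), 2393 bp from the polyamine oxidase gene PAO5 (AT4G29720) and 1261 bp from the protease gene NANA (AT3G12700). Of the 10 strongest peaks of each list, 7 were partners of each other, and all 10 of each had a partner somewhere in the other list. Among the 1000 strongest of each, 757 DIG1 peaks and 753 DIG2 peaks had a partner.

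Peaks of both factors lay outside genes and close to gene ends more often than under random placement. Outside but at most 1000 bp from a protein-coding gene end lay 50.8% of DIG1 peaks (49.9 to 51.8%) and 49.9% of DIG2 peaks (49.1 to 50.7%), against 20.4% under random placement for each list. Inside protein-coding genes lay 28.6% of DIG1 and 29.1% of DIG2 peaks, against 54.2% at random for each list. For all of these shares the permutation p was 0.002, the smallest possible, and the adjusted p was 0.00212. Farther from genes lay 20.6% of DIG1 and 21.0% of DIG2 peaks against 25.4% for each list at random, but the direction depended on the choice of peaks and distance. With nearness set at 500 bp the share was above random for DIG2 (33.9% against 32.5%, two-sided permutation p = 0.002, the smallest possible), while DIG1 (33.2% against 32.5%, p = 0.0959) and the 1000 strongest DIG2 peaks at 1000 bp (26.4% against 25.3%, p = 0.46) lay above random without passing the test. DIG1 peaks without a partner were inside genes more often than those with one, at 42.1% of 347 against 28.2% of 10996 (Fisher's exact test, two-sided, odds ratio 1.85, p = 6.22e-08). For DIG2 the shares were 31.8% of 2672 and 28.4% of 10768 (Fisher odds ratio 1.18, p = 0.00061). Farther from genes lay 5.19% of DIG1 peaks without a partner and 21.1% of those with one. For DIG2 these shares were 23.5% and 20.4%. The Fisher tests did not account for peak strength, and peaks without a partner were mostly weak ones. Among the 1000 strongest peaks, the share inside genes was 22.5% for DIG1 and 19.9% for DIG2.

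**Figure D1:**
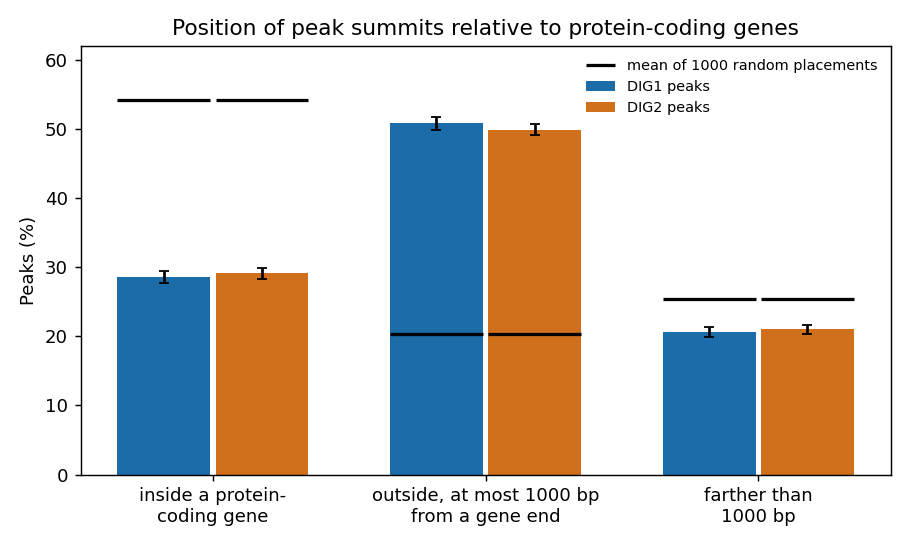
Share of DIG1 (blue) and DIG2 (orange) peaks, in percent, by position of the strongest summit relative to protein-coding genes, with 95% Wilson intervals as error bars and the mean of 1000 random placements as black lines. Peaks near gene ends make up 50.8% and 49.9%, against 20.4% at random, and peaks inside genes 28.6% and 29.1%, against 54.2%.

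Peaks found in only 1 list were mostly weak ones in that list. In the DIG1 list, 2268 of the 2269 peaks in the strongest 20% of the list and 1998 of the 2268 in the weakest 20% (88.1%) had a DIG2 partner (Fisher's exact test, two-sided, p = 1.44e-83). In the DIG2 list all 2688 peaks of the strongest 20% had a DIG1 partner, and 860 of 2688 in the weakest 20% (32.0%), a difference whose Fisher's exact p was too small for the software to represent. Over 10 bins of equal size by rank, sharing of DIG2 peaks was 100% in the strongest 4 bins and 23.3% (21.1 to 25.6%) in the weakest. The strongest DIG1 peaks that touched no DIG2 peak lay inside AT3G48510 (rank 1772), at AT1G76400 and AT1G76405 (rank 2392), at CRR6 (AT2G47910), a gene for chloroplast NDH complex assembly, and NET3C (AT2G47920) (rank 3585), at AT2G29605 (rank 3675) and at AT5G20100 (rank 3681). The strongest DIG2 peaks that touched no DIG1 peak were weaker within their list, the first at rank 5431. They lay 1539 bp from the cytochrome P450 gene CYP71B20 (AT3G26180), at the proton pump gene HA4 (AT3G47950), inside APT3 (AT4G22570), 1141 bp from AT4G00155 and inside the polyamine oxidase gene PAO2 (AT2G43020).

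**Figure D2:**
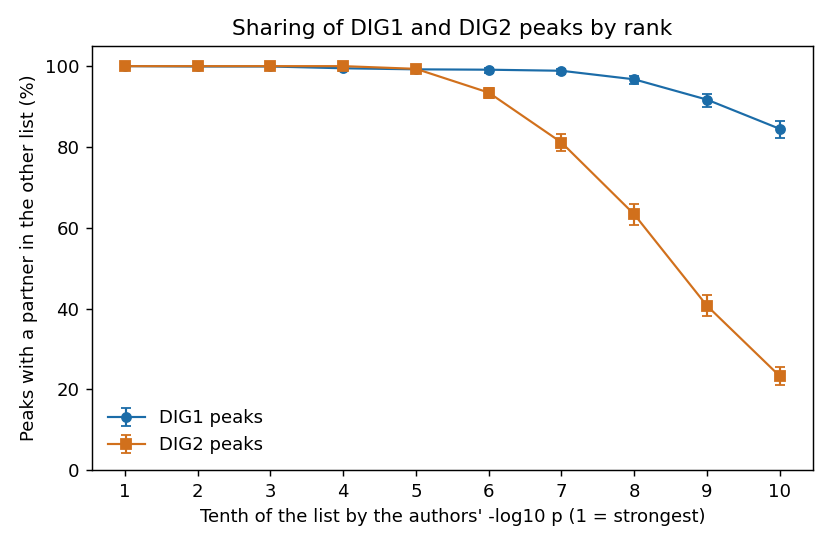
Percent of peaks with a partner in the other list (y axis) in 10 bins of equal size by the authors' −log10 p (x axis, 1 the strongest), for DIG1 (blue circles) and DIG2 (orange squares), with 95% Wilson intervals. The weakest bin stands at 84.5% for DIG1 and 23.3% for DIG2.

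At the level of genes, 9797 of 27444 protein-coding genes (35.7%) had a DIG1 summit at a gene end, 11045 (40.2%) a DIG2 summit and 9408 both. Independent lists of these sizes would share 3943 genes, so the observed number was 2.39 times as large (Fisher's exact test, two-sided, odds ratio 237, with a p too small for the software to represent). A further 389 genes had a DIG1 summit alone and 1637 a DIG2 summit alone. The counts depended on the window around genes, with 6232 DIG1 and 7121 DIG2 genes for 500 bp outside the gene only, and 14878 DIG1 genes for 3000 bp outside and 500 bp inside. A summit between neighbouring genes was counted for both. The Fisher tests of gene lists and families below treat genes as independent. Their p-values can be too small where members are neighbours, as the CBF genes among the cold regulators are by locus number.

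Genes of the core ABA pathway had summits more often than other genes, though for receptors and kinases this depended on the window around genes. Of 9 clade A PP2C phosphatase genes, which encode negative regulators of ABA signalling, 8 had summits of both factors (Fisher adjusted p = 0.00324 for DIG1 and 0.00738 for DIG2), with the strongest at ABI1, AHG3 (folds 8.92 and 12.3 for DIG1 and DIG2) and HAI2 and none at ABI2. Of 14 ABA receptor genes 10 had summits of both (Fisher adjusted p = 0.0144 and 0.0339), led by PYL8, PYL7 and PYL5, while PYL3, PYL10, PYL11 and PYL12 had none. The receptor call was lost for both factors with the 500 bp window (28.6% and 35.7%, Fisher adjusted p = 0.557 and 0.406) and the 3000 bp window (adjusted p = 0.133 and 0.206), and for DIG2 also with the nearest gene end, the strongest summit alone and random lists of matched intergenic length (resampling adjusted p = 0.0819). Of 10 SnRK2 kinase genes 8 had summits of both (Fisher adjusted p = 0.009 and 0.0262), among them SNRK2.3, SNRK2.5 and SNRK2.8, while SNRK2.2 and SNRK2.9 had none. The SnRK2 call was lost for both factors with the 500 bp window (30% and 40%, Fisher adjusted p = 0.718 and 0.335), the 3000 bp window (adjusted p = 0.151 and 0.238) and the strongest summit alone (adjusted p = 0.0519 and 0.0693), and no SnRK2 gene was reached by the 1000 strongest peaks of either list.

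Among 30 ABA-related transcription factor genes, 25 had DIG1 and 26 DIG2 summits (Fisher adjusted p = 9.77e-07 and 1.31e-06). After ABF3, the strongest were at the heat shock factor gene HSFA6B (DIG1 rank 72, DIG2 rank 28) and NF-YB2, which encodes a subunit of a CCAAT-box binding complex (ranks 113 and 39). ABI3, ABI4, AREB3 and MYB2 had no summit. The 16 genes of ABA synthesis and breakdown did not pass the test, with 7 for DIG1 and 10 for DIG2 (Fisher adjusted p = 0.603 and 0.0903), and CYP707A2, an ABA hydroxylase gene, at DIG2 rank 760. With the nearest gene end this list passed for DIG2 (62.5%, Fisher adjusted p = 0.0404). The 27 dehydration and cold effector genes did not pass either, with 13 and 15 (Fisher adjusted p = 0.236 and 0.128). Even so, the dehydrin genes ERD10 (ranks 17 and 11) and COR47 (ranks 39 and 43) were among the strongest peaks, and this list passed among the 1000 strongest peaks (25.9% of members, Fisher adjusted p = 0.000359 for DIG1, and 22.2%, adjusted p = 0.00162 for DIG2). All 7 cold regulator genes had summits of both factors (Fisher adjusted p = 0.00174 and 0.00329), including CBF1, CBF3 and the zinc-finger gene ZAT12, and this call was lost for DIG1 among the 1000 strongest peaks (Fisher adjusted p = 0.0607) and for DIG2 with the stricter threshold and the 3000 bp window (adjusted p = 0.054 and 0.0653).

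Genes of light signalling, the circadian clock and photosynthesis also had summits more often than other genes. Of 25 light signalling genes 21 had DIG1 and 20 DIG2 summits (Fisher adjusted p = 4.97e-06 and 0.000318), led by PIF3 (ranks 391 and 96), HFR1 and PIF5, which encode bHLH proteins of the dark and shade responses. CHS, ELIP2, HYH and PIF7 had none. Of 17 clock genes 14 and 15 had summits (Fisher adjusted p = 0.000318 and 0.00023), led by GI (ranks 87 and 76), LUX and CCA1, with none at ELF3 or RVE4. Of 17 photosynthesis genes 14 and 13 had summits (Fisher adjusted p = 0.000318 and 0.00805), led by the light-harvesting genes LHCA2, LHCA4 (ranks 135 and 174) and LHCB6, while LHCA3, LHCB1.1 and LHCB1.2 had none. Of 11 chlorophyll synthesis genes 8 and 9 had summits (Fisher adjusted p = 0.0297 and 0.0147), led by HEMA1 for glutamyl-tRNA reductase (ranks 450 and 213), CHLH and PORC, with none at CHLD or CHLI1. The photosynthesis call was lost for DIG2 with equal list lengths and with the stricter threshold (52.9% each, Fisher adjusted p = 0.157 and 0.129), and for both factors with the 500 bp window (adjusted p = 0.0601 for DIG1 and 0.432 for DIG2) and among the 1000 strongest peaks. The chlorophyll synthesis call was lost for both factors with the nearest gene end (Fisher adjusted p = 0.0502 and 0.0688), the 500 bp window (adjusted p = 0.182 and 0.202) and the 1000 strongest peaks.

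Other hormone pathways showed similar shares. In the auxin pathway 23 of 27 genes had summits of both factors (Fisher adjusted p = 1.24e-06 and 1.38e-05), led by the repressor genes IAA16 (ranks 263 and 103), IAA19 (ranks 211 and 161) and IAA6, and those without a summit included ARF7, PIN2 and PIN4. In the ethylene pathway 16 and 17 of 22 genes had summits (Fisher adjusted p = 0.00139 and 0.00162), led by EBF2 and EBF1, whose F-box products target EIN3, and by ACS8. In the gibberellin pathway 12 and 14 of 18 genes had them (Fisher adjusted p = 0.0163 and 0.00304), led by the receptor gene GID1B (ranks 337 and 131) and the DELLA repressor genes RGL1 and RGA, with none at GA20OX1, GA2OX8, GA3OX2 or RGL2. In the brassinosteroid pathway 11 of 14 had summits of both (Fisher adjusted p = 0.00289 and 0.00816), led by BAS1, BES1 and ROT3, with none at DET2, BR6OX1 or BR6OX2. In the jasmonate pathway 15 and 17 of 20 had them (Fisher adjusted p = 0.00141 and 0.000295), led by the repressor genes JAZ5, JAZ3 and JAZ1, with none at JAZ8, LOX2 or VSP1. The ethylene, gibberellin, brassinosteroid and jasmonate calls were lost for both factors among the 1000 strongest peaks, and the brassinosteroid call also with the 3000 bp window (Fisher adjusted p = 0.133 and 0.206) and, for DIG2, the 500 bp window (adjusted p = 0.0934). Salicylate and defence genes did not pass, with 9 and 10 of 16 (Fisher adjusted p = 0.128 and 0.0903), and NPR4, WRKY40 and NPR3 the strongest, but passed for both factors with the nearest gene end (68.8% each, adjusted p = 0.00332 and 0.0103).

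Transcription factor families ranged from 44.8% to 80.0% of members. The family lists were matches on gene symbols and were not cleaned, so some members may belong to other families. In the ERF family 44 and 45 of 58 genes had summits (Fisher adjusted p = 1.51e-08 and 8.97e-08), led by RAP2.4 (ranks 69 and 40), RAP2.7 and CBF1. In the BBX and CONSTANS-like family 23 and 24 of 30 had them (Fisher adjusted p = 3.17e-05 and 5.78e-05), led by COL9, BBX29 and BBX28. In the WRKY family 47 and 54 of 71 had them (Fisher adjusted p = 1.63e-06 and 1.51e-08), led by WRKY7, ABO3 and WRKY38. In the homeobox-leucine zipper family 26 and 31 of 48 had them (Fisher adjusted p = 0.0147 and 0.00218), led by HB-2, HAT1 and HAT2. The NAC family had 46 and 51 of 99 (Fisher adjusted p = 0.0347 and 0.0319), led by NAP, NAC041 and NAC047, and the MYB family 56 and 66 of 125 (Fisher adjusted p = 0.0485 and 0.00805), led by MYB3, MYB44 and MYB102. Against random lists with matched intergenic length the NAC calls by Fisher's test (resampling adjusted p = 0.0819 and 0.0862) and the DIG1 call of the MYB family (resampling adjusted p = 0.0921) were lost. Other losses included the NAC calls with the 3000 bp window (Fisher adjusted p = 0.339 and 0.438), the MYB calls with the 500 bp window (adjusted p = 0.276 and 0.396), the MYB and WRKY calls among the 1000 strongest peaks, and the homeobox-leucine zipper call there for DIG1 (adjusted p = 0.0779) and with the 500 bp window for DIG2 (adjusted p = 0.0748). Heat shock factors did not pass, with 10 and 12 of 20 (Fisher adjusted p = 0.247 and 0.122), with HSFA6B, HSFA8 and HSFC1 the strongest, but passed for DIG1 with the stricter threshold (50%, adjusted p = 0.029) and for DIG2 with the 500 bp window (50%, adjusted p = 0.0367). Of 177 genes named as transcription factors, 103 and 114 had summits (Fisher adjusted p = 1.51e-08 and 6.5e-09), led by GATA1 (ranks 18 and 20). This list was a text match on gene names and was not cleaned, so some members may not be transcription factors. It also overlaps the family lists, for example at WRKY12 and WRKY31.

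The list of cytosolic ribosomal protein genes was the only one with a share below that of other genes, 14 and 15 of 54 (25.9% and 27.8%, Fisher adjusted p = 0.165 and 0.0854), which did not pass the test. It passed as lower for both factors with the nearest gene end (16.7% each, Fisher adjusted p = 0.0226 and 0.00553) and the 3000 bp window (adjusted p = 0.024 and 0.0159), and for DIG2 with the stricter threshold (adjusted p = 0.0131) and equal list lengths (adjusted p = 0.0143). Its strongest member, RPS2 (AT4G26090), is a disease resistance gene that shares a symbol with ribosomal proteins and lies beside ABI1, followed by RPL23AB and RPL23AA. Without 5 such resistance genes and 12 organellar ones, chosen after seeing the data, 9 and 10 of 37 had summits (Fisher unadjusted p = 0.171 and 0.13). In all, 21 of 26 lists passed for each factor, each with a higher share. The same 8 lists for both factors passed under every alternative tried, namely the clade A PP2C genes, ABA-related transcription factors, light signalling, the clock, the auxin pathway, the ERF and BBX families and the genes named as transcription factors. For each factor the other 13 lost the call under at least 1 alternative, most often among the 1000 strongest peaks (11 for DIG1 and 9 for DIG2).

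**Figure D3:**
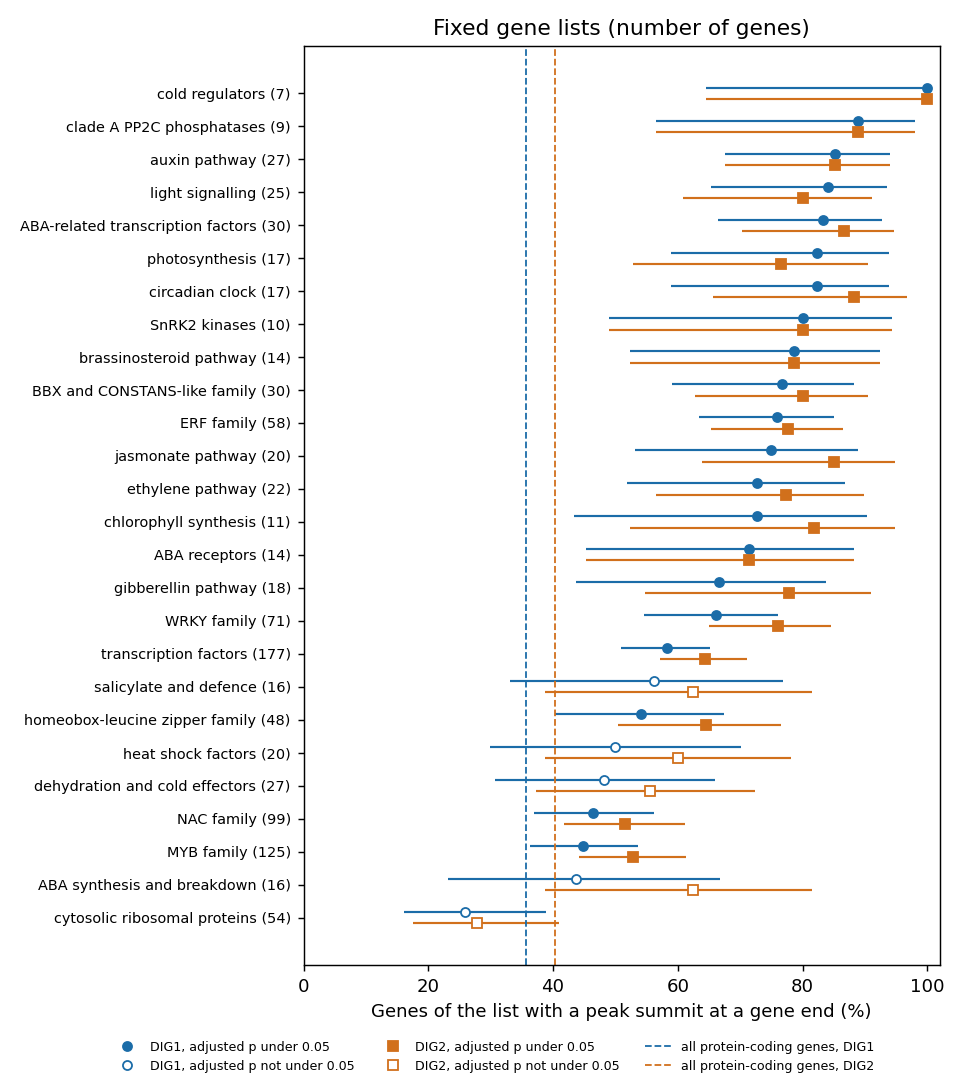
Percent of the genes of each fixed list with a DIG1 (blue circles) or DIG2 (orange squares) summit at a gene end, with 95% Wilson intervals; filled symbols have an adjusted p under 0.05 and dashed lines mark all protein-coding genes, 35.7% and 40.2%. The number of genes is in parentheses, and 21 of 26 lists lie above the lines with filled symbols for each factor.

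The test between DIG1 and DIG2 passed for few lists. In 24 of 26 lists the exact McNemar test gave an adjusted p over 0.05. In the MYB family 10 genes had a DIG2 summit alone and 0 a DIG1 summit alone, and among genes named as transcription factors the numbers were 12 and 1 (exact McNemar adjusted p = 0.0444 for each). The test assumes an even split, while the DIG2 list is longer over all genes. Set against all other genes, neither split passed the test (Fisher's exact test, two-sided, adjusted p = 1 for both, an alternative added after seeing the data), and neither passed with lists of equal length.

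The genes named by the labels were examined as a check on the fusions. The DIG1 label names AT3G45810, which the gene table lists as the NADPH oxidase gene RbohJ, and no summit of either list lay within 3000 bp of it. AT3G48510, the number under which DIG1 is remembered from outside the labels, was added before the data were examined. It carried a DIG1 peak (chromosome 3, 17967548 to 17968510) wholly inside the gene, with summits of fold 6.82 and 6.67. The peak covered 77.8% of the gene and ranked 1772 of 11343, and no DIG2 peak touched the gene. AT5G50360, the DIG2 label's gene, carried a DIG2 peak (chromosome 5, 20505366 to 20507076) over 78.1% of the gene, with a summit of fold 6.99 inside it and a summit of fold 9.71 outside. The DIG1 list held only a peak beside that gene (20506397 to 20507059), with its summit 8 bp from the outer DIG2 summit. Both lists had a summit beside AT3G48510, at 17969479 for DIG1 and 17969480 for DIG2.

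**Figure D4:**
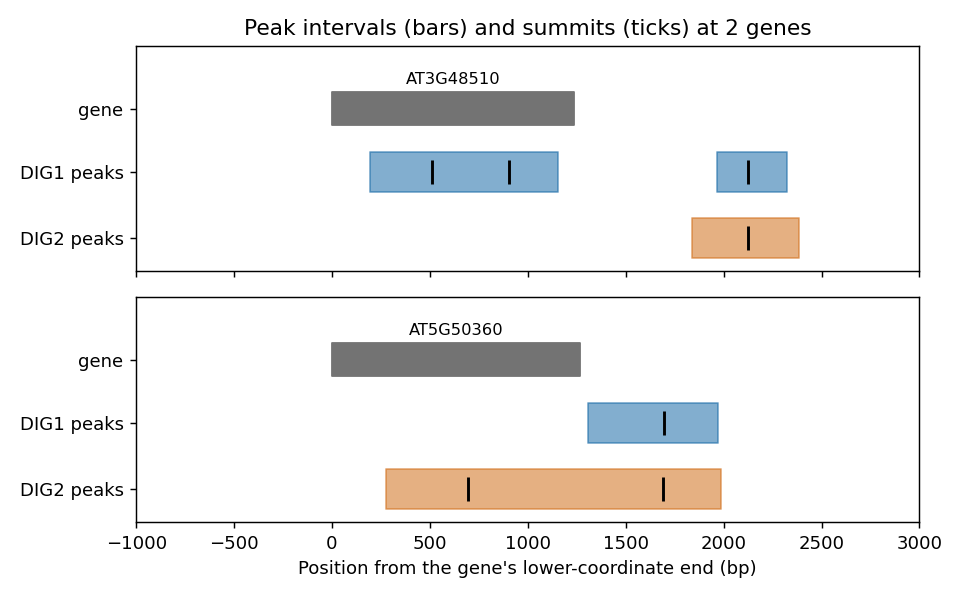
Peak intervals (bars) and summits (black ticks) of the DIG1 (blue) and DIG2 (orange) lists at AT3G48510 and AT5G50360, in bp from the lower-coordinate end of each gene (grey). The DIG1 list alone covers 77.8% of AT3G48510 and the DIG2 list alone covers 78.1% of AT5G50360.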

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

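The explanations below were tested after the patterns were seen, except that placement relative to gene ends was planned before the data were examined.

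The MYB family and the genes named as transcription factors drew attention because genes with a summit in 1 list alone were split unevenly between DIG1 and DIG2 (exact McNemar adjusted p = 0.0444 for both). The 10 MYB genes with a DIG2 summit alone included MYB28, a regulator of glucosinolate synthesis, MYB58, MYB52 and MYB101, and the 12 genes named as transcription factors with a DIG2 summit alone included WRKY12, WRKY31, TCP2 and HSFA9. The single gene of that list with a DIG1 summit alone was DOF4.3. Set against all other genes, neither split passed the test (Fisher's exact test, adjusted p = 1).

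DIG2 peaks without a DIG1 partner touched no DIG1 peak in 2669 cases, against 347 DIG1 peaks that touched no DIG2 peak. Strong DIG2 peaks that DIG1 lacks were looked for by whole peaks at the top of the list. Of the 2688 peaks in the strongest 20% of the DIG2 list, 0 were among the 2669. The sharing by rank had already shown this, so the count is no separate test. This count misses a DIG2 summit without a DIG1 counterpart in a peak that touches a DIG1 peak. The DIG2 peak of rank 1259 is an example. It has a summit inside AT5G50360 (−log10 p of 215), a gene that no DIG1 peak touched. Of the 2669, 9 (0.337%) lay in the stronger 50% of the DIG2 list, which the sharing by rank had also shown already. A place in the weaker 50% does not measure how close a peak lies to the authors' threshold. The 2669 peaks had a median −log10 p of 24.6, and the strongest of them reached 111.7. Weak sites that pass the threshold in 1 list only may account for part of the difference, but these counts do not test it. The lists' depths were unknown, and whether some of the 2660 in the weaker 50% are sites of DIG2 but not DIG1 stays open.

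The overlap of the lists was weighed against 2 technical explanations. That both lists merely lie near gene ends was argued against by placement at the same distance from random gene ends, which gave at most 15.2% of DIG1 peaks with a partner against the observed 96.9%. The random ends were drawn from all protein-coding genes. Whether both lists favour the ends of the same subset of genes was therefore not tested. Regions that any GFP precipitation enriches remain open, because no control peak list was used here. Cytosolic ribosomal protein genes, as one group of heavily transcribed genes, held a DIG1 summit in 25.9% of cases in the fixed list and 24.3% in the list cleaned after seeing the data, which leaves all other regions untested, so this explanation cannot be told apart from shared binding. Binding of both factors to the same sites is a hypothesis that the GFP sample's own peaks would test.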

How the results depend on the processing

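Of the alternatives below, the strongest summit alone and the Fisher comparison between the factors were added after seeing the data. No paired analysis was possible because each group held 1 sample and the results came from peak lists. Sharing kept its direction and its side of the threshold under all alternatives, at 75.7 to 97.6% of DIG1 peaks and 73.0 to 89.7% of DIG2 peaks, as did the shares inside genes and near gene ends and the contrast of the strongest and weakest 20%. The motif alternatives were not run, and alternatives that name a start site used both gene ends. With the 1000 strongest peaks, 1094 DIG1 genes, 1040 DIG2 genes and 775 shared genes had summits, and 11 and 13 lists passed. Fewer peaks were tested there by construction. The window of 500 bp gave 6232, 7121 and 5817 genes, and that of 3000 bp gave 14878 DIG1 and 14452 shared genes and a count of 2 DIG2 summits at AT3G48510 in place of 1, as a narrower or wider window must. The share of peaks farther from genes was above random with nearness at 500 bp (33.2% for DIG1, two-sided permutation p = 0.0959, and 33.9% for DIG2, p = 0.002) and for the 1000 strongest DIG2 peaks (26.4%, p = 0.46); the cause was not tested. The number of lists that differed between the factors, 2, fell to 0 with equal lengths, the 1000 strongest peaks, every other gene window, the strongest summit alone and the Fisher comparison. Among single lists, the shares of SnRK2 genes for both factors (0%) and of MYB genes for DIG1 (2.4%) fell below other genes with the 1000 strongest peaks, and the cause was not tested. So did 2 that had not passed, both for DIG1: ABA synthesis and breakdown with the 1000 strongest peaks (0%) and dehydration and cold effectors with the 3000 bp window (51.9%). Besides these, 54 alternative values for single lists kept their direction but were no longer past the threshold, 13 newly passed it and 346 kept direction and side. Unknown read depth limits any statement on peaks absent from a list.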

Other observations

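All tests below were chosen after seeing the data. Other gene families were searched by grouping genes with the same symbol stem, which can join unrelated genes. Of 117 families with at least 12 members not mainly held by the fixed lists, 11 had summits more often than other genes for DIG1 and 11 for DIG2, and 4 less often for each (Fisher's exact test, two-sided, Benjamini-Hochberg over 234 tests). CIPK kinase genes, whose products act with calcium sensors, had DIG1 summits in 19 of 21 cases and DIG2 summits in 18 (Fisher adjusted p = 6.73e-05 and 0.00103), with CIPK15 at ranks 91 and 71. SAUR genes, early auxin-responsive genes of cell elongation, had them in 15 of 16 cases for both (Fisher adjusted p = 0.000241 and 0.0007), with SAUR15 at ranks 910 and 811. Arabinogalactan protein genes (AGP) had them in 22 and 24 of 30 cases (Fisher adjusted p = 0.000928 and 0.0007). UDP-glycosyltransferase genes (UGT) had them in 33 and 37 of 58 cases (Fisher adjusted p = 0.0152 and 0.00686). Families with fewer summits included the small cysteine-rich LCR genes, with 11 and 16 of 80 (Fisher adjusted p = 0.0007 for DIG1 and 0.00301 for DIG2), the related SCRL genes, with 2 and 4 of 27 (Fisher adjusted p = 0.0126 and 0.045), and genes named for embryo-defective mutants (EMB), with 24 and 29 of 112 (Fisher adjusted p = 0.0154 and 0.0192).

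MicroRNA genes had summits at their ends in 69 of 326 cases for DIG1 (21.2%) and 80 for DIG2 (24.5%). Among 96 genes of microRNA families known from several flowering plants, 31 (32.3%) had DIG1 summits, against 38 of 230 others (16.5%, Fisher's exact test, two-sided, odds ratio 2.41, p = 0.00269). For DIG2 the counts were 34 (35.4%) and 46 of 230 (Fisher odds ratio 2.19, p = 0.00457). Over all protein-coding genes the shares were 35.7% for DIG1 and 40.2% for DIG2. The microRNA genes were not matched on flanking intergenic length, and a summit counted for one can also lie at a neighbouring protein-coding gene. The strongest members of these families were MIR168a, which targets AGO1 (ranks 538 and 934), and MIR399c of the phosphate response (ranks 862 and 753). Some intervals held long runs of summits. The widest DIG2 interval, chromosome 2 from 18368185 to 18374507, was 6323 bp long with 9 summits and reached AT2G44500. Both lists had an 8-summit interval that overlapped the centromere protein gene CENP-C (AT1G15660).

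The DIG1 peak over AT3G48510 drew attention as the strongest of the DIG1 peaks that touched no DIG2 peak. The gene's number is the one under which DIG1 is remembered, while the DIG1 label names AT3G45810. Its −log10 p of 176 lay above the median DIG1 peak (53.8) and was not close to the authors' threshold of 16. The peak was picked out for its strength, so this was known beforehand and is no separate test. A candidate explanation is the fusion transgene read as its endogenous gene. Among 544 genes with a DIG2 summit inside and no DIG1 peak touching them, AT5G50360 held place 1 by its inside summit. Its −log10 p was 215, against 89.2 for the next gene, APT3. Among 123 genes with a DIG1 summit inside and no DIG2 peak touching them, AT3G48510 held place 1 (176, against 140 for AT1G76405). Both peaks were known before these orders were made, so the places do not test the explanation. AT3G45810, the gene of the DIG1 label, had no summit of either list within 3000 bp. Binding of each factor within its own gene was not tested and stays open, as does which gene the DIG1 fusion was made from. An exchange of the names of the 2 lists cannot be told apart from correct names, because the 0 DIG1 summits inside AT5G50360 bear on it only if each fusion marks its own gene.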
